A study of Mus musculus with 8 samples.

How the data were processed

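The samples were CD8 T cells of OT-1 mice, animals whose CD8 T cells carry a single transgenic receptor for an ovalbumin peptide. Per the labels' protocols, activated cells were incubated for 4 h with ID8 cells, a mouse ovarian cancer line, loaded with that peptide, at 30 T cells per target cell, and were then collected by magnetic separation. The targets had been made either to overexpress PD-L1, the ligand of the inhibitory receptor PD-1, or to be depleted of it. Total RNA was labelled with biotin for a 3' expression array of mouse genes, 1 array per sample.

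The deposited values were 1 log2 expression value per probe set and array, running from 3.60 to 15.24. The log2 scale was read from the values; the method by which the authors summarised and normalised the probes was not given in the sources used here. At the same rank, sorted values of the 8 arrays lay within 0.167 of each other, so the distributions were nearly equal as deposited, and a change shared by most genes could be hidden. Arrays correlated with each other at 0.985 to 0.997. The number of arrays, 4 per group, limits the precision.

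Of 22690 probe sets, 64 were control probe sets and were left out of the tests. Of the other 22626, the platform annotation gave 1 gene symbol for 20380, several for 691 and no symbol for 1555; no gene was named from a probe set with several. The 29 Entrez identifiers not found in the reference table kept their symbol, and 0 symbols needed updating. This gave 12393 genes, 4956 of them with several probe sets, and the probe set with the highest mean over the 8 arrays stood for its gene. Genes with a mean under 6.87, the 40th percentile of the means of all non-control probe sets, were not tested, which removed 4390 and left 8003. Cd69, an early activation marker planned as a named gene, had no probe set with a single symbol here and was not analysed here.

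Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The comparison of targets held the mouse as a fixed block. The pairing comes from the series design, which states that T cells of each of 4 mice were divided between the targets, and from the sample titles, which give the mouse. Deviations of an animal's 2 arrays from their group means correlated across genes at 0.82 in mouse A, 0.16 in B, 0.61 in C and 0.64 in D. On this measure each array of mouse B, but of no other mouse, correlated better with an array of another animal. The deviations also hold each mouse's difference between targets. Across genes, that of mouse B correlated with those of A, C and D at -0.62, -0.60 and -0.51. The low value alone therefore does not decide whether the pairing of mouse B holds. Differences between mice were tested by limma's moderated F test with the target as covariate, and each mouse was then set against the mean of the other 3, a comparison added after the data were examined. Each mouse has 1 array per target, so this test measures differences between animals against the spread between co-cultures of the same animal's cells.

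Fixed before the data were examined, 29 gene lists covered T cell functions (22 lists) and markers of other cells (7 lists). The 24 with at least 5 tested members were tested with camera from limma at a preset correlation between genes of 0.01, adjusted over these lists. An estimated correlation and fry, also from limma, were alternatives. For list means, an exact sign-flip test over 4 mice has 16 sign patterns and cannot go below a two-sided p of 0.125.

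The genes named were, by a rule fixed before the data were examined, the 10 with the smallest p in each direction when fewer than 10 passed, up to 4 members of each list with the smallest p, a set of checkpoint and effector genes, the 8 with the smallest p between mice, and Xist with Y chromosome genes. Genes named outside it are said to be so. Alternatives were no block for the mouse, the mouse as a random block, quantile normalisation, median centring, other filters, the mean of a gene's probe sets, all probe sets, eBayes without a trend or with robust variances, array weights, other thresholds, and leaving out each mouse. A fit with the mean of the tumour marker genes as a covariate was added after the data were examined. The table held 0 columns of other samples, and scan dates were not used here.

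The steps were tested on simulated data with known changes in 8003 genes. For the comparison of targets, 65.7% of genes changed by 1.19-fold, 91.0% of those changed by 1.41-fold and 100% of those changed by 2-fold were recovered, with 10 false calls. For the comparison of mice the shares were 7.46%, 65.7% and 95.5%, with 2 false calls. A list shifted by -0.1 was called, with 0 others. The simulated noise was independent between genes, so this says nothing about false list calls where genes of a list move together.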

Results

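RNA was measured on 8 arrays of activated OT-1 CD8 T cells after 4 h with peptide-loaded ID8 ovarian cancer cells. T cells of 4 mice, A to D, were each divided between PD-L1-overexpressing and PD-L1-depleted targets, which gave 4 arrays per group. All values are deposited log2 expression values, and differences between targets are overexpressing minus depleted. Mice accounted for 74.6% of the variance of the tested genes, targets for 4.97% and the remainder for 20.5%.

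The first comparison asked which T cell genes differ after contact with targets that carry much or little PD-L1. None of the genes of T cell attack named here passed, and their differences were small. Gzmb, a granule protease that triggers death of the target, averaged 14.63 ± 0.057 (SD, n = 4) with PD-L1-overexpressing and 14.64 ± 0.064 (SD, n = 4) with PD-L1-depleted targets. Gzmb lay near the highest value on the arrays, 15.24, where a difference may be compressed. Ifng, the main cytokine of activated CD8 T cells, averaged 13.10 ± 0.18 and 13.09 ± 0.16 (SD, n = 4 each). The pore-forming Prf1 differed by 0.020 (SE 0.033), the death ligand Fasl by -0.051 (SE 0.041), Tnf by -0.011 (SE 0.042) and the growth factor gene Il2 by -0.028 (SE 0.074). The widest 95% interval among these, that of Il2, ran from -0.195 to 0.140 on the log2 scale.

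No gene passed the test between targets. The limma fit with the mouse as a block called 0 of 8003 genes higher and 0 lower, with a smallest adjusted p of 0.9995, and 228 genes had an unadjusted p under 0.05, where 400.2 would be expected by chance. The 95% interval lay inside 1.5-fold in either direction for 7956 genes (99.4%) and inside 2-fold for 7980 (99.7%). The same direction in all 4 mice was seen for 842 genes (10.5%), where chance gives 12.5%. Mouse B decided the count of 0 genes: without it 176 genes passed, 152 higher and 24 lower, and in mouse B 150 of the 152 and 19 of the 24 went the opposite way. Among the 176 were 8 of the 17 tested tumour cell markers. That marker list was fixed beforehand, and whether the other genes called came from T cells or from target RNA was not tested.

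PD-L1 was altered in the target cells, so its transcript Cd274 is here a reading of the T cells and of any target RNA left with them. Cd274 averaged 9.65 ± 0.33 (SD, n = 4) with PD-L1-overexpressing and 9.70 ± 0.31 (SD, n = 4) with PD-L1-depleted targets, a difference of -0.042 (SE 0.041). Pdcd1, which encodes the receptor PD-1, differed by 0.032 (SE 0.044), with levels of 10.40 and 10.37. Pdcd1lg2, the gene of the second PD-1 ligand, differed by 0.048 (SE 0.048). Among other checkpoint receptors, Lag3 differed by -0.021 (SE 0.040) and Ctla4 by -0.022 (SE 0.020). Havcr2, the gene of TIM-3, differed by 0.078 (SE 0.039) and was higher in 4 of 4 mice. The transcription factor genes Tbx21 and Eomes differed by -0.002 (SE 0.041) and -0.073 (SE 0.057). None of these passed (limma adjusted p = 0.9995 for each).

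**Figure D1:**
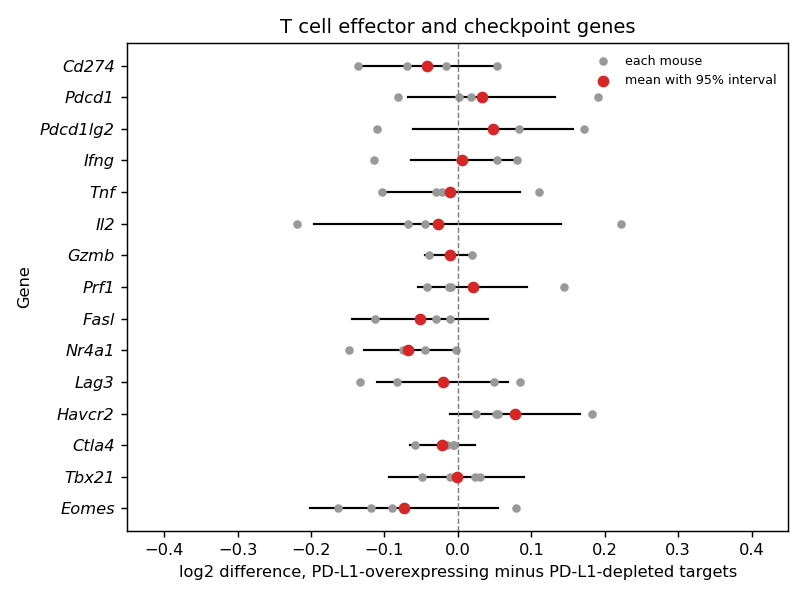
Differences in log2 expression between PD-L1-overexpressing and PD-L1-depleted targets (horizontal axis) for T cell effector and checkpoint genes (vertical axis). Red points are means over 4 mice, black lines 95% intervals and grey points single mice; Nr4a1 lay lower in 4 of 4 mice and Havcr2 higher in 4 of 4, and none of the genes passed the adjusted test.

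Genes with the smallest p, none of which passed, included Cx3cr1, a chemokine receptor gene of effector cells, at -0.30 (SE 0.058), and Lfng, a modifier of Notch receptors, at -0.15 (SE 0.037). Tinagl1 (-0.20), Igfbp5 (-0.17), Camta2 (-0.15), Ovgp1 (-0.27), Chek2 (-0.21), Slc2a5 (-0.18) and Cd4 (-0.18) were lower in 4 of 4 mice, and Fos (-0.17) in 3 of 4. On the other side, Crebzf (0.15), Aamdc (0.19), Tars (0.11), Rest (0.16), Ccnd2 (0.065), Btf3 (0.056), Rspry1 (0.14), Nr1d2 (0.22) and Ppic (0.15) were higher in 4 of 4 mice, and Celsr1 (0.25) in 3 of 4. Cx3cr1, Ovgp1, Cd4, Celsr1 and Nr1d2 passed in the fit without mouse B, at limma adjusted p from 0.0124 to 0.0289.

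Of the 24 gene lists tested, the early activation response, genes induced within hours of receptor signalling, was the only list called lower. Of its 24 tested members 17 were lower and 7 higher with PD-L1-overexpressing targets, with a median of -0.035, and the list passed camera downward (adjusted p = 0.000424). This call was lost with an estimated correlation (adjusted p = 0.915 with an estimated correlation). Zfp36 differed by -0.18 (SE 0.060), Dusp1 by -0.18 (SE 0.060) and Nr4a1, a reporter of receptor signalling, by -0.068 (SE 0.027). Nr4a1 was lower in 4 of 4 mice, and Zfp36 and Dusp1 in 3 of 4. The list mean differed by -0.039 in mouse A, -0.076 in B, -0.091 in C and -0.0090 in D, with an exact two-sided sign-flip p of 0.125, the smallest that 4 mice allow. No member passed over all genes, and 0 passed adjusted over the list alone.

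Small upward shifts were seen in 2 metabolic and stress lists. Of 19 tested genes of fatty acid oxidation, 17 were higher and 2 lower, with a median of 0.025 (camera adjusted p = 0.0197, and 0.915 with an estimated correlation, which ended the call). Slc25a20, the mitochondrial carnitine carrier, differed by 0.087 (SE 0.037), and Etfa, an electron carrier, by 0.069 (SE 0.029). A second Slc25a20 probe set, with a mean of 8.86, differed by -0.0024. Of 23 tested genes of the unfolded protein and amino acid stress response, 19 were higher and 4 lower, with a median of 0.021 (camera adjusted p = 0.0225, and 0.915 with an estimated correlation, which ended the call). Vldlr differed by 0.12 (SE 0.052) and Asns, asparagine synthetase, by 0.048 (SE 0.025). Both lists also lost the call under quantile normalisation (adjusted p = 0.0832 and 0.118), without mouse B (0.322 and 0.192) and without mouse D (0.132 and 0.237). The stress list also lost it without the mouse as a block (adjusted p = 0.257) and with the mean of each gene's probe sets (adjusted p = 0.0816). No member of either list passed over all genes or adjusted over the list alone.

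The other lists of T cell function did not pass. Cytotoxic granule genes had 8 of 18 higher and a median of -0.0060, cytokines and chemokines 8 of 17 and -0.011, and inhibitory receptors 8 of 14 and 0.0049. Genes of the interferon-gamma response had 15 of 22 higher and a median of 0.0045, and those of glycolysis 12 of 18 and 0.0082. Oxidative phosphorylation genes had 25 of 30 higher (median 0.017, camera adjusted p = 0.118), and passed with no filter (adjusted p = 0.0106), with median centring (0.0239) and without mouse A (0.0206). Cell cycle genes had 12 of 31 higher (median -0.0086, adjusted p = 0.624), and passed downward without mouse B (adjusted p = 0.0264). Over the lists that did not pass, camera adjusted p ran from 0.118 to 0.865. In each of the lists named here 0 members passed over all genes and 0 adjusted over the list alone.

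Markers of the tumour cells gave signal on the T cell arrays, and their differences between targets ran in opposite directions among the mice. Upk3b, a surface gene of mesothelial cells, was higher with PD-L1-overexpressing targets in mice A (9.28 against 7.61), C (9.95 against 8.07) and D (9.78 against 7.96). In mouse B it stood at 7.51 with PD-L1-overexpressing and 9.79 with PD-L1-depleted targets. Fn1, which encodes fibronectin, differed by 1.03 in mouse A, 0.70 in C and 0.73 in D, and by -1.05 in B. Averaged over the 17 tested tumour markers, the difference was 0.49 in mouse A, -0.65 in B, 0.42 in C and 0.42 in D (exact two-sided sign-flip p = 0.625). Of these markers 12 were higher and 5 lower in the mean over mice, with a median of 0.094, and the list did not pass (camera adjusted p = 0.236). It passed without the mouse as a block (adjusted p = 0.0331) and without mouse B (adjusted p = 2.47e-21), where 8 of the 17 genes passed on their own.

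**Figure D2:**
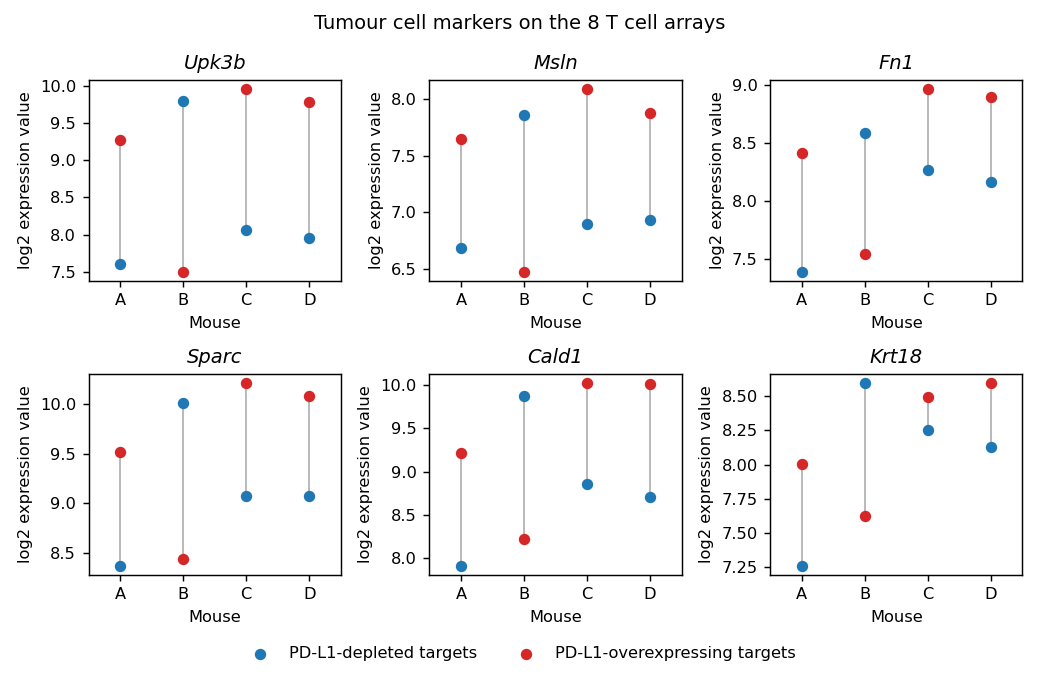
Log2 expression value (vertical axis, range set per panel) of 6 tumour cell markers in each mouse (horizontal axis), with red points for PD-L1-overexpressing and blue points for PD-L1-depleted targets. The red point lies above the blue one in mice A, C and D and below it in mouse B; the genes drawn were chosen after their values were seen.

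Markers of other cells gave no call over all genes between targets. Cd4 passed adjusted over its list of 4 tested CD4 and regulatory T cell markers alone (adjusted p = 0.0369), at -0.18 (SE 0.054) and lower in 4 of 4 mice. The B cell (4 tested), macrophage and dendritic cell (6), NK cell (2), erythroid and platelet (3) and neutrophil (1) lists had 0 members passing adjusted over the list alone.

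The second comparison set the animals against each other, as a measure of the variation the change between targets stands beside. Mouse A stood apart in the granule proteases. Gzmd was 9.17-fold, Gzma 6.06-fold and Gzme 5.44-fold higher in the mean of the other mice than in mouse A. Gzmg stood at 5.86 and 5.58 in mouse A, under the filter of 6.87, so no fold is given, and at 9.31 to 10.14 in the other mice. S100a4, a calcium-binding protein gene of effector and memory cells, was 8.71-fold higher, and the interferon-inducible Ifitm1 and Ifitm3 were 3.45-fold and 2.96-fold higher. Gzmb was also lower in mouse A, by -0.096 on the log2 scale. These genes, except Gzmb, and Erdr1 had the smallest p of the F test; Erdr1 was low in mouse C, 8.72-fold under the highest mouse.

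Of 8003 genes, 2347 (29.3%) passed the limma F test between mice, 77 of them with over 2-fold between the highest and lowest mouse. The count of genes differing between mice was 576 without mouse A and 3555 without mouse B. Set against the mean of the others, mouse A had 1446 genes higher and 1017 lower, mouse B 504 and 237, mouse C 247 and 428, and mouse D 365 and 327. The 2 arrays of an animal come from the same T cells, so the p-values measure the spread between co-cultures, and which property of an animal or its culture differed is not in the labels.

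**Figure D3:**
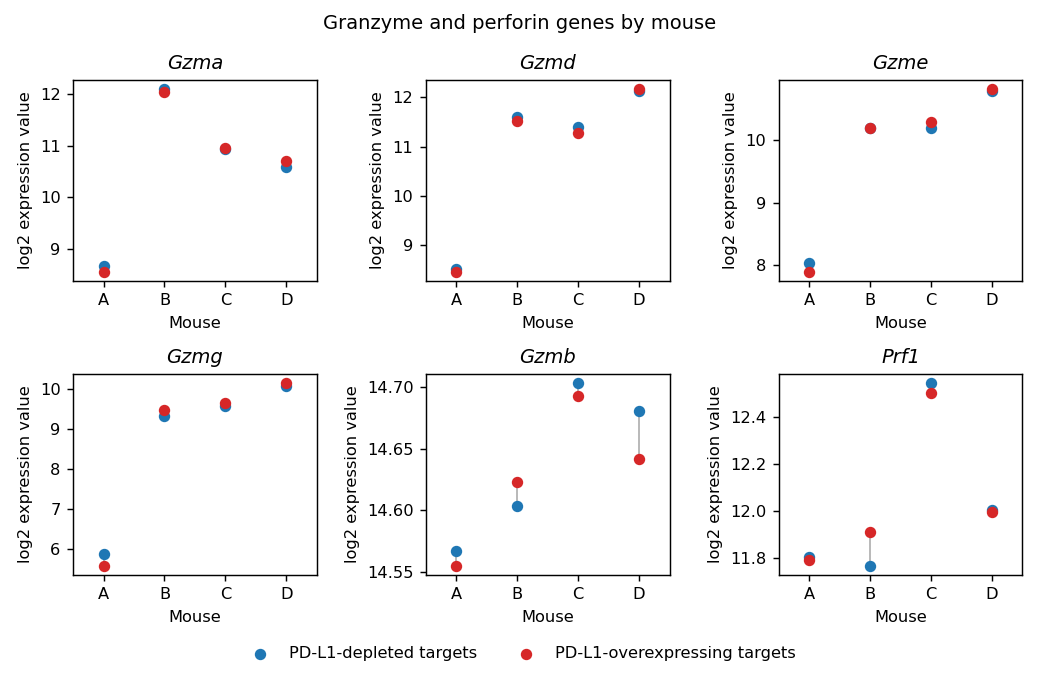
Log2 expression value (vertical axis, range set per panel) of 5 granzyme genes and Prf1 in each mouse (horizontal axis), with red points for PD-L1-overexpressing and blue points for PD-L1-depleted targets. Gzma, Gzmd, Gzme and Gzmg are lowest in mouse A on both arrays, while Gzmb spans a narrow range in all mice, near the top of the arrays' range, where differences may be compressed.

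By list, 11 of 18 cytotoxic granule genes were lower and 3 higher in mouse A than in the other mice, with a median of -0.32. Cholesterol and fatty acid synthesis had 18 of 20 genes lower in mouse A and 0 higher, among them Fdps (-1.58), Mvd (-1.28) and Hmgcs1 (-0.85), enzymes of the sterol pathway. Of the interferon-gamma response 16 of 22 genes were lower and 2 higher, and of the type I interferon response 13 of 20 were lower and 0 higher. Glycolysis had 12 of 18 lower and 2 higher. The heat shock list, whose members are mostly chaperones, went the other way, with 10 of 15 higher and 1 lower. By the F test over all 4 mice, 16 granule genes passed over all genes and 17 adjusted over the list alone, with 18 and 18 for cholesterol and fatty acid synthesis and 20 and 20 for the interferon-gamma response. These 6 lists passed camera in mouse A (adjusted p from 2.04e-16 to 0.000239) and none held with an estimated correlation (adjusted p from 0.159 to 0.217 with an estimated correlation).

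The lists of cytokines and chemokines (7 of 17 higher and 4 lower in mouse A, camera adjusted p = 0.355), inhibitory receptors (5 of 14 higher and 5 lower, adjusted p = 0.509), costimulatory receptors (6 of 12 higher and 2 lower, adjusted p = 0.244) and TCR complex and proximal signalling (4 of 26 higher and 7 lower, adjusted p = 0.400) did not pass in mouse A, and their members went both ways. Against the mean of the other mice, Il3 was higher by 1.80, Il2 by 1.17 and Csf2 by 0.83, while the chemokine gene Ccl5 differed by -1.26. Cd5 and Cd6, surface regulators of receptor signalling, were higher by 0.72 and 0.57. Cd274 was higher in mouse A by 0.54.

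Other gene groups stood out in mice B, C and D. In mouse B, 16 of 22 interferon-gamma response genes were higher and 0 lower, 16 of 31 cell cycle genes were lower and 0 higher, and the immediate early genes Fos and Jun were higher by 1.21 and 1.01. Of 14 B cell markers on the array, 4 were tested, namely H2-Aa, H2-Ab1, Cd74 and Ighm. Their mean was 10.02 and 10.05 on the arrays of mouse A and 10.19 and 10.28 in C. It was 10.92 and 10.96 in D and 11.29 and 11.35 in B. The mean of the interferon-gamma response genes put the mice in the same order (10.71 and 10.73, 10.78 and 10.82, 11.15 and 11.18, 11.21 and 11.22). H2-Aa had the widest range of the 4 markers (6.77 to 10.21 over the arrays), so it weighs most in the marker mean. Single markers did not all follow this order: Ighm was highest in mouse D (11.05 and 11.07) and Cd74 lowest in mouse C (11.96 and 11.99). Under the filter, Cd79a was lowest in mouse B (6.35 and 6.51), while Blk read 5.90 and 6.05 there against 5.50 and 5.67 in A. Cd79a and Blk are named outside the rule. Whether other cells in the samples account for the shared order was not tested. In mouse C, 11 of 31 cell cycle genes were higher and 0 lower, and 13 of 22 interferon-gamma response genes were lower and 0 higher. In mouse D, 14 of 20 cholesterol and fatty acid synthesis genes and 10 of 20 type I interferon response genes were higher, with 0 lower in either, and 8 of 17 cytokine and chemokine genes were lower and 2 higher. The first 2 of these lists were not particular to mouse D. In mouse C 10 of 20 cholesterol and fatty acid synthesis genes were higher and 0 lower. In mouse B 8 of 20 type I interferon response genes were higher and 0 lower. For both lists the mean of the others includes mouse A, which had the lowest list means. Camera called these lists in their mouse (adjusted p from 2.66e-16 to 2.62e-06), and none held with an estimated correlation (adjusted p from 0.159 to 0.451 with an estimated correlation). Over all 96 tests of a list in a mouse, 0 passed with an estimated correlation.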

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

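The tests of CD3 and CD8 genes and of actin were chosen after the result was seen; the count of granule genes outside the granzyme family was not.

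In each group of 4 arrays, the gap between the farthest array and its neighbour was divided by the range of the group, for the genes and lists named here. Of 234 groups of values, 20 had an array that stood far from the other 3, where chance gives about 11.7, or 1 group in 20, and in 12 of them it was an array of mouse A. Many of these genes were named because they differ between mice. Mouse A was lowest for the mean of the cytotoxic granule list (0.954 with PD-L1-depleted and 0.931 with PD-L1-overexpressing targets), S100a4 (0.940 and 0.932), Ifitm1 (0.887 and 0.848) and Mvd (0.865 and 0.901). With PD-L1-overexpressing targets it was also lowest for Gzmg (0.851) and Btf3 (0.915) and highest for Nr1d2 (0.931), and with PD-L1-depleted targets highest for Ovgp1 (0.883). Mouse C was lowest for Erdr1 (0.981 with PD-L1-depleted and 0.945 with PD-L1-overexpressing targets) and, with PD-L1-overexpressing targets, highest for Pdcd1 (0.898) and lowest for Eif2s3y (0.911), a Y chromosome gene below the filter. Mouse B was highest for Fos with PD-L1-overexpressing targets (0.851) and for Jun with PD-L1-depleted targets (0.898), and lowest for Lpl with PD-L1-overexpressing targets (0.852). Mouse D was highest for the mean of the unfolded protein and amino acid stress list with PD-L1-depleted targets (0.834).

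Granule genes were lower in mouse A, with a median of -1.06 over the 11 called lower there and of -0.315 over all 18 tested. A lower share of CD8 T cells is argued against as the whole cause for these 11 genes, though not as a part of it. The evidence is Cd3d, Cd3e, Cd3g, Cd247, Cd8a and Cd8b1, 6 genes chosen after the values were seen. Their median in mouse A minus the others was -0.140 (-0.278 to -0.0125). Of these, Cd3d read 13.90 to 14.03 over the arrays, where a difference may be compressed, while Cd247 read 10.27 to 10.62. RNA quality is argued against by the actin control, whose signal at the 3' end minus that at the 5' end was 0.197 in mouse A, inside the 0.169 to 0.244 of the other arrays. Cross-hybridisation among granzyme genes is argued against as the whole cause of the list result by 4 granule genes outside that family that were also lower. They do not show that the granzyme probe sets read separate genes, so part of the granzyme differences may be shared signal. A difference between the animals or their cultures stays open as a hypothesis, and no biological explanation was tested.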

How the results depend on the processing

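The fit with the tumour marker mean as a covariate and the comparison of each mouse with the others were chosen after the data were examined; the other settings were planned. The count of genes changed between targets was 0 with and without the mouse as a block (no replicate block, 0), with the mouse as a random block, and under each other scaling, filter, probe set choice, variance model, array weighting and threshold. Leaving out 1 mouse gave 0 to 176, with 176 without mouse B and 0 without A, C or D. The tumour marker covariate gave 3, all lower (Zfp36, Hspa1b and, named after its value was seen, Pigt); the cause was not tested. Of the gene lists between targets, 3 passed; 0 passed with an estimated correlation, 0 with fry, 1 with quantile normalisation, and 1 to 4 without 1 mouse, lowest without mouse D and highest without A.

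The early activation response passed under every planned setting except the estimated correlation (adjusted p = 0.915) and fry (adjusted p = 0.442). Fatty acid oxidation was lost with the estimated correlation (0.915), fry (0.442) and quantile normalisation (0.0832), and ran from 0.0338 to 0.322 without 1 mouse. The unfolded protein and amino acid stress response was lost with the estimated correlation (0.915), fry (0.442), quantile normalisation (0.118), no block for the mouse (0.257) and the mean of a gene's probe sets (0.0816), and ran from 0.0206 to 0.237 without 1 mouse. Removing the block ended no other call and added the tumour markers (0.0331). The count of genes differing between mice ran from 576 without mouse A to 3555 without mouse B, and 1652 to 2185 under the other settings. Named genes were recomputed without the block, with quantile normalisation, with the mean of probe sets and without each mouse: 16 values moved by over 1 SD, all with the mean of probe sets, and 8 gained a call, all without mouse B. Lists gained a call in 7 cases: oxidative phosphorylation upward with no filter (0.0106), median centring (0.0239) and without mouse A (0.0206), cell cycle downward without mouse B (0.0264), heat shock downward with the covariate (0.0224), and the tumour markers upward without the block and without mouse B (2.47e-21). Except where stated, the causes were not tested. The planned pseudocounts were not run, since the values were already on a log scale. Signal over background per probe set was not used here, so low values have no detection limit beyond the filter.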

Other observations

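The tests on the tumour markers, the covariate fit and the count of splits for genes were chosen after the result was seen; the counts of splits for lists and of pairings for mice were not. The estimated correlation was a planned setting, and the bounds its p is read against for the early activation list were chosen after the result was seen.

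Of 14 B cell markers on the array, 4 were tested and the others lay under the filter. These 4, H2-Aa, H2-Ab1, Cd74 and Ighm, passed the limma F test between mice, over all genes and adjusted over the list alone. Between targets 0 passed, and the list was too short for camera. Under the filter the markers went both ways, with Cd79a lowest in mouse B (6.35 and 6.51) and Blk lowest in mouse A (5.50 and 5.67), both named outside the rule. H2-Aa averaged 10.16 in mouse B and 9.07 in D, against 7.14 in C and 6.77 in A, the last under the filter of 6.87, while it differed by -0.077 (SE 0.062) between targets. Between the highest and lowest mouse, H2-Ab1 differed 1.78-fold, Cd74, which encodes the class II invariant chain, 1.65-fold and Ighm 1.78-fold. NF-kB targets were higher in mouse B for 9 of 15 genes and lower for 1, and lower in mouse D for 7 and higher for 0 (camera adjusted p = 3.86e-06 and 3.90e-07; adjusted p = 0.217 and 0.197 with an estimated correlation). Xist ran from 14.18 to 14.26 over the 8 arrays. Of the Y chromosome genes, Eif2s3y, Kdm5d, Uty, Usp9y, Zfy2, Uba1y and Tspy-ps lay below the filter, with 6.12 in Tspy-ps as the highest value, and Sry read 7.37 to 7.53, above the filter, by the probe set used and 4.03 to 4.22 by its other probe set.

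In the fit without mouse B, the genes furthest apart between targets, chosen after their values were seen, were Cpe at 2.12 (SE 0.059), Mgst1 at 2.09 (SE 0.052), Lpl at 1.81 (SE 0.068) and Upk3b at 1.79 (SE 0.051), all higher with PD-L1-overexpressing targets. Of these, only Upk3b was on the list of tumour markers, and whether the RNA of the others came from T cells or from targets was not tested. Across genes, the difference between targets in mouse B correlated with that in mice A, C and D at -0.62, -0.60 and -0.51, while A, C and D correlated with each other at 0.49 to 0.58; genes are not independent replicates.

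The tumour markers were higher with PD-L1-overexpressing targets in mice A, C and D and lower in mouse B. A candidate explanation is RNA of ID8 cells left after the magnetic separation, with Sparc and Cald1, chosen after their values were seen, reaching log2 values of 10.21 and 10.02; that over the 17 tested markers mouse B mirrored the mean of the others (r = -0.974 across genes, 10 markers opposite to all 3 others) restates the reversal and does not decide it. Exchanged labels of the 2 arrays of mouse B would give the same r and cannot be told apart from unequal carry-over. The tumour marker mean in B ran opposite to the others, and the early activation mean did not (-0.0764). Other T cell lists, read after their values were seen, went both ways. The means of cell cycle (0.093 in B) and of cytokines and chemokines (0.108 in B) ran opposite to the other mice. These differences are small, so the sign of a list mean in mouse B does not decide it. Better survival of PD-L1-overexpressing tumour cells would raise the markers in every mouse. As labelled, mouse B went against this, with a marker mean lower by -0.65. Since exchanged labels or unequal carry-over in mouse B are not excluded, better survival stays open. The exact p of 0.625 decides nothing, since 4 mice cannot go below 0.125. The real split gave 0 genes, so that 8 of the 8 splits that part every mouse gave at least as many says nothing, and 8 are too few for a share under 0.05; the highest other, 290 genes, exchanges mouse B and restates its opposite direction, a structure of the samples already seen.

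The early activation response was lower with PD-L1-overexpressing targets at a preset correlation. With the tumour marker mean as a covariate the camera p was 2.43e-07 at that preset correlation, so at this setting the covariate did not end the call. The covariate fit was not run with an estimated correlation, so it does not decide whether tumour RNA took part. Genes of this list moving together may account for the call: with an estimated correlation the p was 0.0584, which does not decide it. The difference in PD-L1 between the targets, which the design names, stays open and was not tested apart from this comparison. Of the 8 splits, 5 gave as many lists as the real 3, with 3 as the highest other, and 8 are too few for a share under 0.05.

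Between mice, 1 of the 24 pairings of an array of each target gave as many genes as the real 2347, the real one itself. The highest other gave 647. This is the smallest share that 24 pairings allow, so it argues against a chance pairing but does not exclude it.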
